A study of Homo sapiens with 6 samples.

How the data were processed

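Total RNA from 6 samples of BE(2)-C cells was measured on Affymetrix arrays with the WT terminal labelling kit, per the labels' protocols, with 3 samples per hairpin and 6 days of infection. The deposited table holds 1 column of normalized signal per array, which was taken as log2 because the values ran from 0.275 to 13.2, as summaries on that scale do; the log base is not stated in the file, so each log2 change and fold rests on that reading. GCRMA and HOMER are the tools in the submitters' processing notes, which give no version, and the role of HOMER is not given in the sources used here. GCRMA is a background correction, quantile normalization and probe summary method; it pulls dim probe sets towards a floor and forces similar distributions on all arrays, so a change shared by most genes would not appear. Arrays have no read depth, and no detection call per probe set was used here.

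Groups were taken from the sample titles. The source name of the third GFPsh sample repeats that of the second, and the title was used. No pair of arrays held the same values. The hairpin sequences were not used here.

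Probe sets were named through the platform annotation, which gave 1 gene symbol for 16098 probe sets, several for 0, and none for 37519, which are unnamed here. The Entrez identifiers of all 16098 were found in the RefSeq gene table of GRCh38.p14, used for names only, and 0 symbols changed. No coordinates are given because the files name no build. Probe sets with a mean over the 6 arrays above the 30th percentile of named probe sets (3.98) were kept, 11268 in all, and the brightest probe set stood for each gene, leaving 10542 of 14884 genes. Of 411 genes with over 1 probe set above the filter, 89 changed, and 18 of these had a probe set of opposite sign, none of them among the 4 named genes with over 1 such probe set (B2M, ISL1, RPS18 and WARS1).

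Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Changes are PUS7sh minus GFPsh, errors after ± are SDs between samples, and SE is limma's moderated standard error. Single values were compared with exact two-sided permutation tests. The 29 gene lists were fixed before the data were examined, as were the comparisons, the naming rule and most of the other settings tried. They hold 866 distinct genes, of which 459 were measured, and 25 lists with at least 8 measured members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. Of the 10 lists called, 6 rose and 4 fell, and 4 calls held with an estimated correlation. Genes were named by a rule: PUS7, MYC and MYCN, the 12 largest rises and 12 largest falls past the threshold with groups that did not overlap (leaving out symbols of non-coding and unnamed loci), every measured pseudouridine synthase, and up to 2 rises and 2 falls per list. Figures were drawn with matplotlib 3.10.9.

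The procedure was tested on simulated data for this comparison with the 10542 genes, 200 of them changed. It recovered 18% of changes of 0.3 log2 units, 70% of 0.5, 88% of 1 and 100% of 2, and 6.757% of the calls were false. In the data 2384 genes were called, far more than the 200 changed here. The adjustment therefore asked for a less strict unadjusted p in the data than in the simulation. These recovered shares do not give the sensitivity of the real comparison. A list shifted by 0.3 was called in 20 of 20 draws, and 0 of 460 tests of unshifted lists were called. The simulated genes varied independently of each other, so these list counts do not cover false calls among correlated genes.

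Alternatives covered the signal filter, quantile normalization, median centring, the choice of probe set, the variance model, array weights, the replicate number as a block, leaving out each array, thresholds, probe sets in place of genes, and the test of a list. The list tests without ATF4 list members and the fit of every probe set above the filter were chosen after seeing the data.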

Results

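Gene expression was measured on Affymetrix arrays in BE(2)-C cells, an established human neuroblastoma cell line, 6 days after infection with a lentivirus that expressed a short hairpin RNA (shRNA). Of the 6 arrays, 3 came from cells with a hairpin against GFP (GFPsh), a jellyfish gene used here as the control target, and 3 from cells with hairpin number 33 against PUS7 (PUS7sh). PUS7 is a pseudouridine synthase, an enzyme that converts uridine to pseudouridine in tRNA and other RNA. The submitters describe the 3 samples of each hairpin as independent. The table held 53617 probe sets per array, with column medians from 4.08 to 4.12 on the log2 scale. Arrays of the same group correlated with Pearson r from 0.985 to 0.987 across probe sets, and arrays of different groups from 0.980 to 0.983, where probe sets are not independent replicates. The number of arrays limits the precision of every value, both groups were infected, and no uninfected cells were analysed here.

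The first question was whether the targeted transcript was lower in the cells with its hairpin. PUS7 fell to 58.2% of its GFPsh level (95% interval 50.05% to 67.7%). Its probe set, 17061467, read 8.22, 8.21 and 8.30 log2 units in the GFPsh samples and 7.28, 7.50 and 7.61 in the PUS7sh samples. The means were 8.24 ± 0.05 and 7.46 ± 0.16 (SD, n = 3 each), a log2 change of -0.78 (SE 0.09) with a Benjamini-Hochberg adjusted p of 0.00126 in limma. An exact two-sided permutation test of the 3 against 3 values gave p = 0.1, the smallest p this design allows. A second PUS7 probe set, 17118266, lay below the signal filter, at 3.79 ± 0.07 in GFPsh and 3.53 ± 0.30 in PUS7sh (exact two-sided permutation p = 0.4, n = 3 each).

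The main comparison asked which transcripts differed between cells with the PUS7 hairpin and cells with the GFP hairpin. Many of the largest falls were in genes of the amino acid and stress response, such as ATF5 and ASNS, and the largest rises included the neuropeptide gene GAL, the hypoxia-inducible factor gene EPAS1 and several genes of cholesterol metabolism. ASNS, which encodes asparagine synthetase, fell from 8.82 ± 0.03 to 5.93 ± 0.10 (SD, n = 3 each; limma adjusted p = 1.19e-06), a 7.41-fold difference. GAL, which encodes galanin, rose 4.80-fold, from 6.43 ± 0.36 to 8.70 ± 0.10 (SD, n = 3 each; limma adjusted p = 0.00015). Of 10542 genes tested, 1097 rose and 1287 fell at a Benjamini-Hochberg adjusted p under 0.05 in limma.

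**Figure D1:**
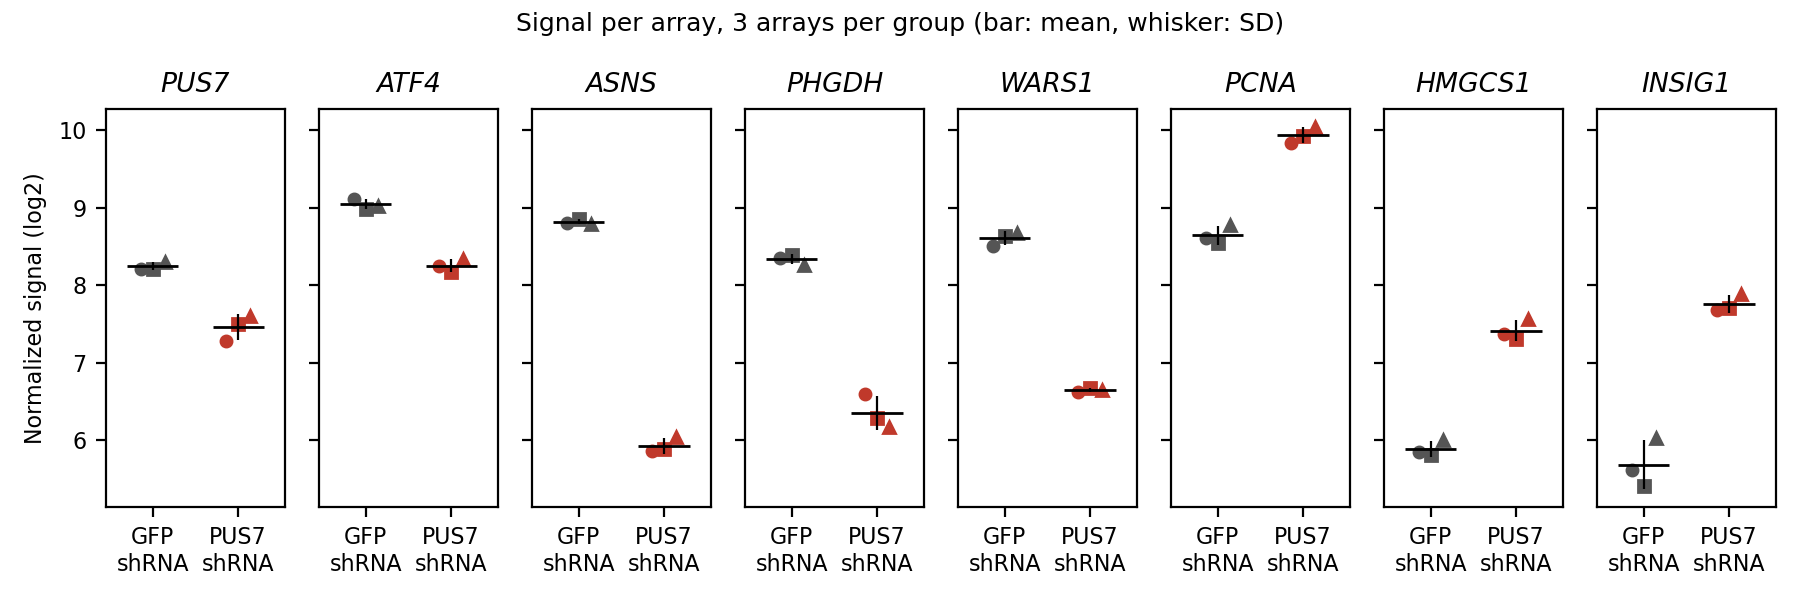
Log2 signal of 8 genes on each of the 6 arrays, with GFPsh and PUS7sh samples as separate points whose shape marks the replicate, a bar at each group mean and whiskers of 1 SD (n = 3). PUS7, ATF4, ASNS, PHGDH and WARS1 lay lower in all 3 PUS7sh samples than in any GFPsh sample, and PCNA, HMGCS1 and INSIG1 lay higher.

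Among the genes that rose, MINAR2 changed most, from 5.48 ± 0.09 to 7.77 ± 0.04 (SD, n = 3 each; limma adjusted p = 4.55e-06), which is 4.88-fold. EPAS1 rose 4.28-fold and INSIG1, an endoplasmic reticulum protein gene that restrains sterol synthesis, rose 4.20-fold. The other genes among the 12 largest rises were ARHGAP36 (log2 change 1.62), SOAT1, which esterifies cholesterol (1.60), TMEM245 (1.56), HMGCS1 (1.53), MSMO1 (1.51), CHST15 (1.49), the growth factor gene HGF (1.38) and the transcription factor gene KLF2 (1.36). Among the 12 largest falls, ATF5 fell 8.40-fold, from 9.003 ± 0.007 to 5.93 ± 0.24 (SD, n = 3 each; limma adjusted p = 9.2e-06). GDF15, a secreted stress cytokine gene, changed by -2.74 and DDIT4, an inhibitor of mTORC1 signalling, by -2.57. The others were TRIB3 (-2.41), SHMT2 (-2.32), SESN2 (-2.25), MFAP4 (-2.22), STC2 (-2.20) and DDIT3 (-2.15). The naming rule also took TM6SF1 and ULBP1, whose GFPsh means were 6.58 and 7.20. Their PUS7sh means of 2.81 and 3.62 lay below the filter of 3.98, so neither the size of their fall nor their rank is given.

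In total 2384 genes changed, of which 33 rose and 91 fell at least 2-fold, and the median log2 change of all genes tested was 0.0036. The 3 PUS7sh values lay wholly above or below the 3 GFPsh values in 4311 genes, 40.9% of those tested, where chance gives 10%. Leaving out GFPsh replicate 2 lowered the count of changed genes to 1568, with 723 that rose and 845 that fell. The count that rose was 727 without GFPsh replicate 1 and 717 without PUS7sh replicate 2.

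Targets of ATF4, the transcription factor of the integrated stress response, fell together. Of 20 measured members, 19 fell, none rose and 1 did not pass, and all 20 fell when adjusted over the list alone (limma camera adjusted p = 7.49e-112, median log2 change -1.97; adjusted p = 0.00928 with an estimated correlation). ATF5 and ASNS had the largest falls in the list. The list includes ATF4 itself. Further members among the 19, singled out here after their values were seen, were ATF4 at -0.79 (limma adjusted p = 0.000463), PCK2 at -1.97, PSPH at -1.63, PSAT1 at -1.60 and CTH at -1.37. The member that did not pass over all genes was ATF3, also chosen after its value was seen, at -0.23 (limma adjusted p = 0.112). Over the list alone the limma adjusted p of ATF3 was 0.0363, the same as its unadjusted p.

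The list of cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, also fell as a group. Of 18 members measured, 12 fell, 1 rose and 5 did not pass, and adjusted over the list alone 14 fell and 2 rose (limma camera adjusted p = 2.33e-27, median -0.62; adjusted p = 0.0227 with an estimated correlation). The 5 include AIMP1 (0.015), a protein of the synthetase complex that is not itself a synthetase. WARS1 fell 3.89-fold, from 8.61 ± 0.09 to 6.65 ± 0.02 (SD, n = 3 each; limma adjusted p = 7.79e-06), and MARS1 changed by -1.49. KARS1 was the member that rose, by 0.38. The list shares no measured member with the ATF4 list, as all 18 stayed without ATF4 list members. Whether ATF4 acts on these genes was not tested, so their fall cannot be taken as separate from that of the ATF4 targets.

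The serine, glycine and one-carbon list was called lower, but its members divided. Of 17 measured, 6 fell, 2 rose and 9 did not pass, with the same 6 and 2 adjusted over the list alone (limma camera adjusted p = 2.42e-07; adjusted p = 0.399 with an estimated correlation). SHMT2 changed by -2.32 and PHGDH, the first enzyme of serine synthesis, by -1.98, while TYMS, which makes thymidylate for DNA synthesis, rose by 0.72 and SFXN1 by 0.32. The list's mean was -0.45 and its median 0.0097, so mean and test were negative and the median was not. Without the members shared with the ATF4 list, 13 were measured and the limma camera adjusted p was 0.891.

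The p53 target list was likewise called lower, with changed members in both directions. Of 17 measured, 3 fell, 4 rose and 10 did not pass, with the same 3 and 4 adjusted over the list alone (limma camera adjusted p = 0.00172; adjusted p = 0.920 with an estimated correlation). GDF15 and SESN2 had the largest falls, TRIAP1 rose by 0.84 and CCNG1 by 0.44. The mean was -0.21 and the median 0.0019, which differ in sign. Without the members shared with the ATF4 list, GDF15 and SESN2, the direction of the test turned, with a median of 0.063 and a limma camera adjusted p of 0.354.

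Genes of DNA replication and mitosis were higher in PUS7sh cells. In the G1/S and replication list, 19 of 28 measured members rose, 0 fell and 9 did not pass, and 21 rose adjusted over the list alone (limma camera adjusted p = 8.83e-17, median 0.45; adjusted p = 0.0135 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, rose 2.45-fold, from 8.65 ± 0.12 to 9.94 ± 0.10 (SD, n = 3 each; limma adjusted p = 0.000127), and CCNE2, a cyclin of the G1/S transition, rose 2.32-fold. In the G2/M and mitosis list, 22 of 31 rose, 0 fell and 9 did not pass, and 25 rose adjusted over the list alone (limma camera adjusted p = 5.27e-11, median 0.36; adjusted p = 0.0432 with an estimated correlation). The spindle checkpoint genes TTK and MAD2L1 rose by 0.94 and 0.84. The replication-dependent histone list had 0 members named here.

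Cholesterol synthesis genes rose, with 10 of 17 measured members higher, 1 lower and 6 not passing, and 11 higher and 2 lower adjusted over the list alone. The limma camera adjusted p was 2.82e-11 with a median of 0.36, and the call was lost at adjusted p = 0.212 with an estimated correlation. INSIG1 rose from 5.69 ± 0.31 to 7.76 ± 0.11 and HMGCS1 from 5.89 ± 0.10 to 7.42 ± 0.14 (SD, n = 3 each), while TM7SF2, a sterol reductase gene, fell by 0.45 on the log2 scale.

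The heat shock chaperone list and both ribosome lists were called higher by camera at its preset correlation, though most ribosome genes did not pass and none of these calls held with an estimated correlation. Of 8 heat shock chaperones, 6 rose, 0 fell and 2 did not pass, with the same 6 adjusted over the list alone (limma camera adjusted p = 0.00702, median 0.32; adjusted p = 0.168 with an estimated correlation). HSPH1 rose by 0.78 and HSPB1 by 0.58, and the near-identical HSPA1A and HSPA1B count as separate members although their probes may not tell them apart. Of 43 cytosolic ribosomal protein genes, 5 rose, 0 fell and 38 did not pass, and 3 rose adjusted over the list alone (limma camera adjusted p = 0.0078, median 0.14; adjusted p = 0.265 with an estimated correlation). RPL22 rose by 0.45 and RPS18 by 0.34, and ribosomal protein genes have many processed pseudogenes that can share probes. Of 24 ribosome biogenesis and MYC target genes, 5 rose, 0 fell and 19 did not pass, with the same 5 adjusted over the list alone (limma camera adjusted p = 0.0240, median 0.14; adjusted p = 0.150 with an estimated correlation). That call was also lost after quantile normalization, at a limma camera adjusted p of 0.0529, and MRTO4 (0.40) and RRP12 (0.37) were its largest rises.

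**Figure D2:**
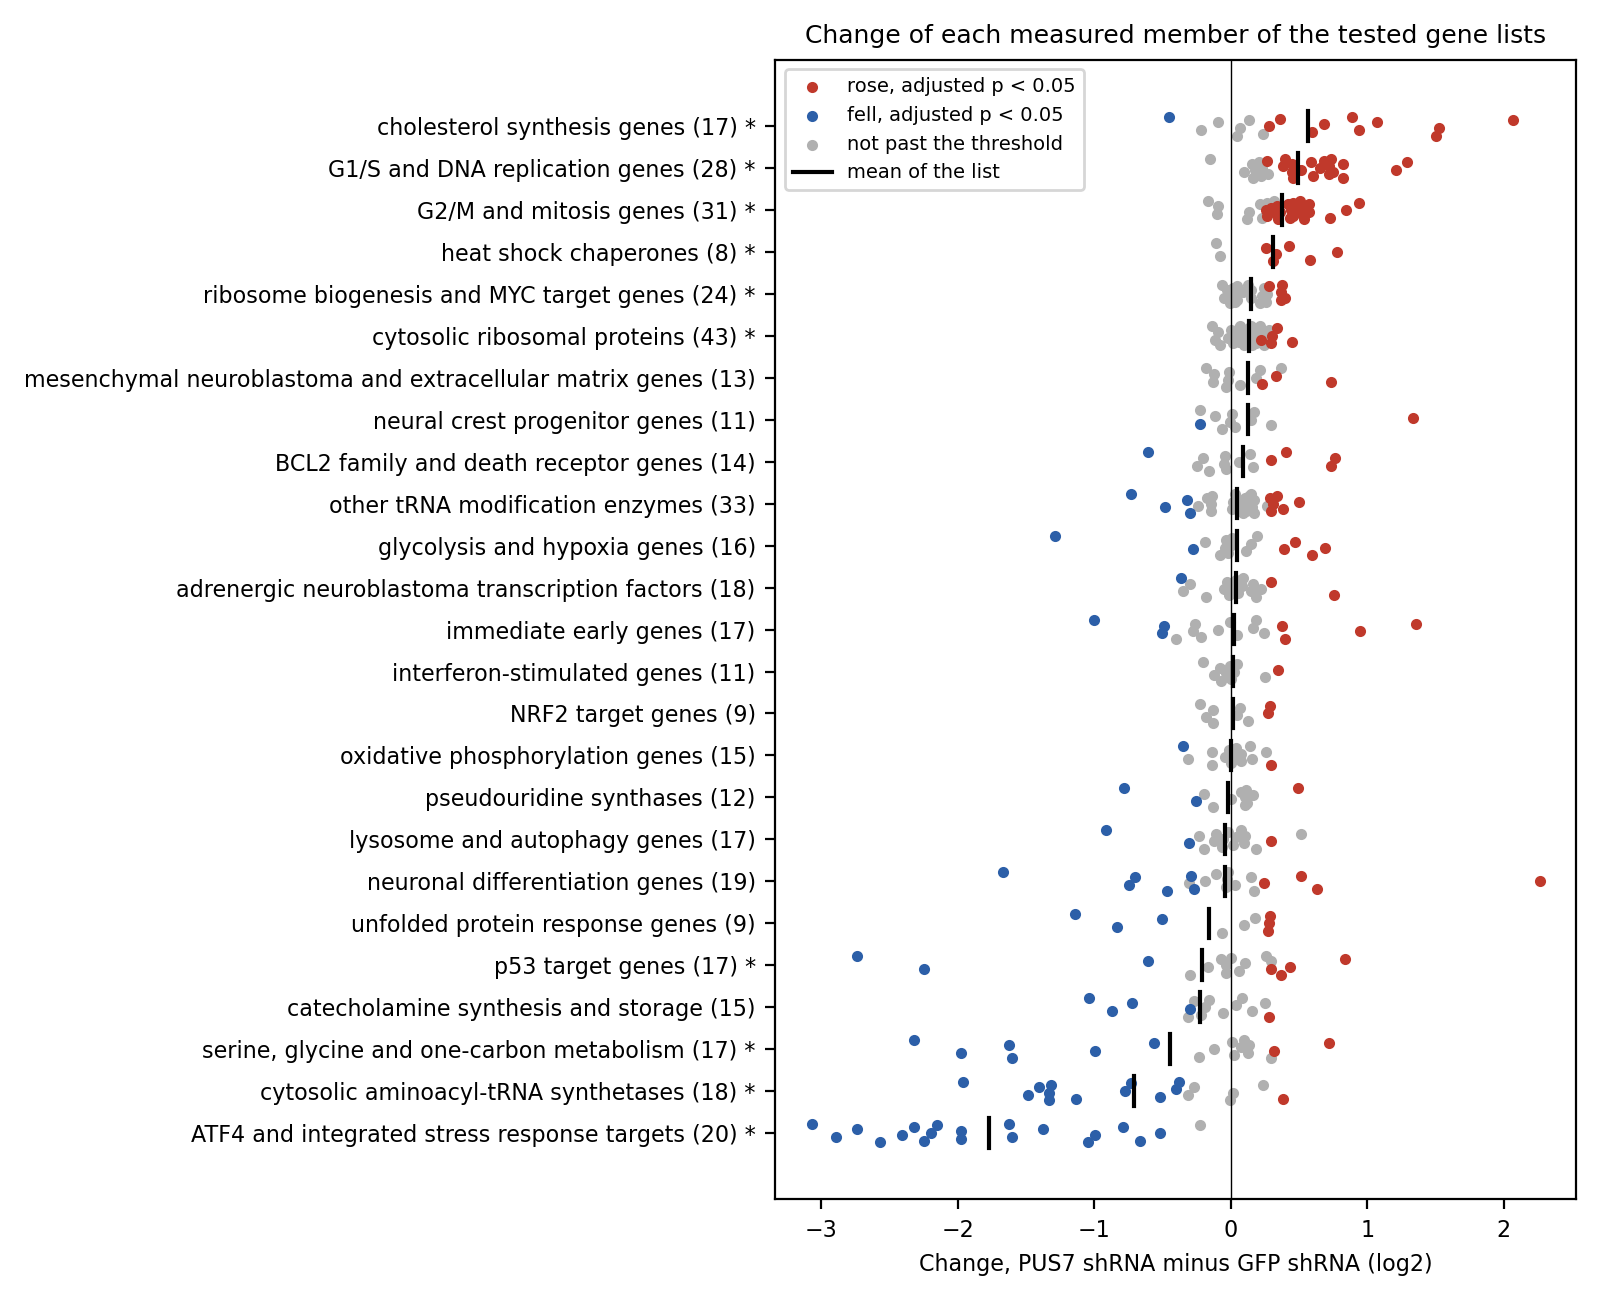
Log2 change (PUS7sh minus GFPsh) of each measured member of the 25 tested gene lists, coloured by whether the gene passed an adjusted p of 0.05, with a black bar at each list mean, the number measured in brackets and a star on lists called by camera. The ATF4 target points lie furthest to the left, and the replication and mitosis points lie mostly to the right of 0.

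None of the 5 lists of neuroblastoma identity genes was called against the other genes by camera, though single members changed. Across all protein-coding genes tested, 23.3% changed. Under fry, which asks whether a list's own genes move on balance one way, 4 of the 5 passed. The limma fry adjusted p was 0.00668 for catecholamine genes and 0.0204 for neuronal genes, both lower. Neural crest genes had a limma fry adjusted p of 0.01003 and mesenchymal genes 0.0380, both higher. The neural crest and mesenchymal medians were only 0.011 and 0.070. Of their members, 9 of 11 and 10 of 13 did not pass, so these calls do not show that most members rose. Of 15 genes of catecholamine synthesis and storage, 4 fell and 1 rose, and 7 fell and 2 rose adjusted over the list alone (limma camera adjusted p = 0.0946, median -0.19). VGF and TH, which encodes tyrosine hydroxylase, changed by -1.04 and -0.87, and CHGB rose by 0.28. Leaving out PUS7sh replicate 3 brought this list's limma camera adjusted p to 0.0299, and using no signal filter brought it to 0.0376. Of 18 adrenergic transcription factor genes, 2 rose and 1 fell, against 1 and 1 adjusted over the list alone (limma camera adjusted p = 0.710), with ISL1 up by 0.76, HAND1 up by 0.29 and TFAP2B at -0.36. Of 13 mesenchymal genes, 3 rose, and the same 3 adjusted over the list alone (limma camera adjusted p = 0.330), among them SNAI2 at 0.73 and S100A6 at 0.33. Of 11 neural crest progenitor genes, LIN28B, a repressor of let-7 microRNA processing, rose 2.53-fold from 7.70 ± 0.06 to 9.04 ± 0.04 (SD, n = 3 each; limma adjusted p = 3.23e-05), and ETS1 changed by -0.22. These were the only changed members of that list, also when adjusted over the list alone (limma camera adjusted p = 0.215). Of 19 neuronal differentiation genes, 4 rose and 6 fell, against 4 and 7 adjusted over the list alone (limma camera adjusted p = 0.431). DCX fell 3.18-fold and L1CAM 1.68-fold, while GAL and DPYSL3 (0.63) rose. MYC had 1 named probe set with a mean of 2.72, below the filter, and MYCN was not analysed here.

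Most pseudouridine synthases other than PUS7 did not pass the test. Of 12 measured, PUS7 and TRUB1 (-0.25, limma adjusted p = 0.0427) fell, RPUSD4 rose by 0.49 (limma adjusted p = 0.00165) and 9 did not pass, with the same counts adjusted over the list alone (limma camera adjusted p = 0.914). The 9 were PUS7L (-0.20), RPUSD3 (-0.13), PUS1 (0.0031), RPUSD1 (0.076), PUSL1 (0.10), TRUB2 (0.10), PUS3 (0.11), RPUSD2 (0.12) and PUS10 (0.16). The list's median was 0.089, its mean -0.016 and its test positive. Of 33 other tRNA modification enzymes, 6 rose and 4 fell, with the same counts adjusted over the list alone (limma camera adjusted p = 0.594). METTL1, the tRNA m7G methyltransferase gene, rose by 0.50 and TRMT10A by 0.38, while DUS1L changed by -0.73 and MTO1 by -0.48.

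The unfolded protein response, BCL2 family, glycolysis and hypoxia, and immediate early lists each held changed genes in both directions. Of all 9180 protein-coding genes tested, 23.3% changed, with 1001 that rose and 1139 that fell. The presence of changed members alone therefore does not mark a list. Of 9 unfolded protein response genes, 3 rose and 3 fell, also adjusted over the list alone (limma camera adjusted p = 0.115). XBP1 (-1.14) and SEL1L (-0.84) fell, and CALR (0.29) and MANF (0.28) rose. The list's median was 0.098, while its mean of -0.16 and its test were negative. With a trended, robust variance its limma camera adjusted p was 0.0313. Of 14 BCL2 family and death receptor genes, 4 rose and 1 fell, also adjusted over the list alone (limma camera adjusted p = 0.264), with BCL2 up by 0.77, BCL2L11 up by 0.74 and PMAIP1 at -0.61. Of 16 glycolysis and hypoxia genes, 4 rose and 2 fell, also adjusted over the list alone (limma camera adjusted p = 0.797). VEGFA fell 2.44-fold, LDHA changed by -0.28, and ANKRD37 (0.69) and PGAM1 (0.60) rose. Of 17 immediate early genes, 4 rose and 3 fell, against 5 and 5 adjusted over the list alone (limma camera adjusted p = 0.914). KLF2 and KLF6 (0.95) rose, DUSP6 fell 2.01-fold and DUSP4 1.41-fold, and the median of -0.0054 differed in sign from the mean of 0.028 and from the test.

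The remaining lists held few changed genes. Of 15 oxidative phosphorylation genes, COX7B (0.30) rose and UQCRC1 (-0.35) fell, against 0 and 1 adjusted over the list alone (limma camera adjusted p = 0.867). Of 17 lysosome and autophagy genes, CTSA (0.30) rose and MAP1LC3B (-0.92) and UVRAG (-0.31) fell, also adjusted over the list alone (limma camera adjusted p = 0.812). Of 9 NRF2 targets, PRDX1 (0.29) and TKT (0.27) rose, also adjusted over the list alone (limma camera adjusted p = 0.812). Of 11 interferon-stimulated genes, B2M (0.35) rose, also adjusted over the list alone (limma camera adjusted p = 0.812), with a median of -0.0047 against a positive mean of 0.016 and a positive test. Lists with under 8 measured members were not tested. Of 6 NF-kB genes none passed, also adjusted over the list alone, the smallest p values being for IL11 (0.36, limma adjusted p = 0.0515) and NFKB1 (0.14). Among markers of other cell types, 0 of 5 Schwann cell and melanocyte genes passed, also adjusted over the list alone, with SOX10 at 0.17 and GFAP at 0.10. Of 6 immune, blood, endothelial and epithelial genes, EPCAM (0.56) rose and CD68 (-0.34) fell, also adjusted over the list alone.

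Of the 86 changed genes chosen by the naming rule other than PUS7, 66 kept their call when any 1 array was left out and none changed sign. The other 20 calls ended in at least 1 of these 6 fits, with 16, 12 and 16 ended without GFPsh replicates 1, 2 and 3, and 12, 15 and 10 without PUS7sh replicates 1, 2 and 3. The highest limma adjusted p came without GFPsh replicate 1 for SFXN1 (0.119), HAND1 (0.117), TKT (0.0880), CD68 (0.0742), PRDX1 (0.0596) and RPL22 (0.0565). It came without GFPsh replicate 2 for CTSA (0.0906) and METTL1 (0.0506). It came without GFPsh replicate 3 for LDHA (0.147), TRUB1 (0.136), COX7B (0.116), MRTO4 (0.0741), S100A6 (0.0705) and RPS18 (0.0519). It came without PUS7sh replicate 2 for ETS1 (0.117), UVRAG (0.114), CHGB (0.103), EPCAM (0.0872), CALR (0.0729) and MANF (0.0623).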

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

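The test below was planned as an alternative, and the listing of its probe sets was chosen after the result was seen. When all 53617 probe sets were tested, 830 of the 37519 without a gene name here changed (332 rose and 498 fell, limma with Benjamini-Hochberg adjustment), a signal outside the gene table that the report's comparisons do not use. In the same fit 766 named probe sets changed. The 830 changed unnamed probe sets held 800 distinct sets of 6 values, since 2113 probe sets of the array share all 6 values with another. Probe set 16670185 changed by -4.45, from a mean of 8.61 to 4.16, and 16979917 by -3.65, from 9.91 to 6.26. Probe set 17010760 rose by 2.15, from 6.36 to 8.50. All of these means lay above the filter of 3.98 used for genes. No explanation was tested.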

How the results depend on the processing

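The list tests without ATF4 list members and the fit of every probe set above the filter were chosen after seeing the data. PUS7 stayed lower and past the threshold in each setting of the gene table, with log2 changes from -0.85 to -0.69 when 1 array was left out. The count of changed genes, 2384, was 1110 at an adjusted p under 0.01 and 124 with a change of at least 2-fold, both by the construction of a stricter threshold. With fewer samples when 1 array was left out, it ran from 1568 to 2006, with 717 to 929 genes that rose and 845 to 1077 that fell. It was 1785 without the filter (1678 shared), 2586 with a stricter one, 2387 after quantile normalization (2239 shared), 2359 with median-centred arrays, where 40.7% of calls rose against 46.0%, 2382 with the mean of probe sets, 2892 with a trended robust variance, 2701 with array weights, 1596 over all probe sets and 2598 over those above the filter. Sample numbers did not pair the arrays: deviations of same-numbered samples correlated at 0.059, -0.0027 and 0.019, and 3 of 6 arrays correlated best with their own number. With the replicate block 1954 genes changed (1852 shared), 10 lists were called and PUS7 had a limma adjusted p of 0.00608. Of the 10 lists called, 4 were called with an estimated correlation. Fry, which does not set a list against other genes, called 17 of the 25 lists tested, the 10 among them, and also the catecholamine, mesenchymal, neuronal, neural crest, unfolded protein response, BCL2 family and NRF2 lists. The camera direction of the p53 list turned from lower to higher without ATF4 list members, as GDF15 and SESN2 left it, with a median of 0.063. In all, 13 of 25 lists and 21 of 99 named genes changed side of the threshold or direction in some setting, and no named gene reversed. The cause was not tested. Dim probe sets limit what can be seen, as for the second PUS7 probe set, MYC and the PUS7sh levels of TM6SF1 and ULBP1.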

Other observations

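All tests in this part were chosen after the result was seen, as were its gene lists. The ERK feedback, DNA repair and let-7 lists were drawn up after changes of some of their members had been seen, so no list p-value is given for them. Of 12 measured feedback genes of the ERK pathway, transcripts that ERK signalling induces, 8 fell, 0 rose and 4 did not pass in limma. DUSP6 fell 2.01-fold, and the log2 changes of ETV5, SPRY4 and ETV4 were -0.96, -0.86 and -0.78. The list shares DUSP4, DUSP5, DUSP6, EGR1 and IER3 with the immediate early list. Of 21 DNA repair genes, 13 rose, 0 fell and 8 did not pass, with UNG, the uracil-DNA glycosylase gene, at 1.15 and RAD51AP1 at 0.70.

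Among 12 measured let-7 target genes, 2 rose (LIN28B, itself a member, at 1.34 and CDC25A at 0.53), 1 fell (ARID3B, -0.34) and 9 did not pass. Of 69 mitochondrial ribosomal protein genes, 9 rose and 4 fell (limma camera adjusted p = 0.133), and of 14 fatty acid synthesis genes, 4 rose and 1 fell (limma camera adjusted p = 0.133). The mitochondrial synthetase and proteasome lists had 0 members named here. By gene type, 23.3% of 9180 protein-coding genes changed (1001 rose and 1139 fell). So did 20.2% of 461 microRNA genes (28 and 65) and 16.1% of 628 long non-coding RNA genes (46 and 55). The median signals of these types were 6.06, 5.13 and 4.84. Whether the microRNA probe sets read mature microRNA or longer transcripts was not tested, so these counts are not counts of changed mature microRNAs.

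Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called as many genes, with 2384 against a highest other of 0. The splits are too few for a share under 0.05. Each other split also mixes both groups, which puts the group difference into its residual spread and lowers its count of genes. The other splits called 2 to 6 lists, against 10 for the real one. Each of them keeps part of the group difference, since its sides hold unequal numbers of PUS7sh arrays. Camera sets a list against the other genes, so these list calls can reflect that part or correlated genes. They therefore do not measure how many of the 10 calls are false.

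The fall of the ATF4 targets, with a list median of -1.97, was set against 3 explanations. An intensity-dependent artefact of normalization is argued against by 10000 random lists matched on signal, whose lowest median was -0.279. For a general loss of transcripts for translation, the cytosolic ribosomal protein genes had a median of 0.139. Its 95% interval of 0.104 to 0.180 came from a bootstrap over genes, which does not measure spread between arrays. That median argues against a loss that takes in ribosomal protein transcripts. It does not speak for other translation genes, as 12 of 18 members of the cytosolic aminoacyl-tRNA synthetase list fell. Whether their fall is separate from that of the ATF4 targets was not tested. An off-target action of the hairpin cannot be told apart from loss of PUS7, because the series has 1 PUS7 hairpin. A second PUS7 hairpin, or a hairpin-resistant PUS7, would separate these, and neither was analysed here.

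The rise of the replication and mitosis lists, with medians of 0.45 and 0.36, exceeded the highest median of the matched random lists, 0.258, which argues against an intensity-dependent artefact. A larger share of dividing cells in the PUS7sh cultures cannot be told apart from a change of transcription within each cell. The 20 DNA repair genes outside both lists had a median of 0.296 (95% interval 0.161 to 0.460, bootstrap over genes). That list was drawn up after rises of some members had been seen, so it decides nothing. Cell counts or cell cycle profiles were not used here.

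PUS7 kept 58.2% of its signal, while genes that no hairpin targeted kept less. If uninfected cells in the PUS7sh cultures held the GFPsh level of a gene, that gene would stay at least as high as their share. Yet 42 genes with a PUS7sh mean above the filter kept less than PUS7 with 95% intervals apart. Among them, ATF5 kept 11.9% and ASNS 13.5%. These values argue against uninfected cells as the whole cause, unless signals between cells reached them or their levels were below GFPsh levels. No uninfected cells were analysed here to show their levels. Of 1050 genes within 0.5 log2 units of the GFPsh level of PUS7, 10 fell further with intervals apart. Larger falls could therefore be read at this signal level. These are other probe sets, so they cannot decide whether the scale was compressed at the PUS7 probe set. Signal from other transcripts at the probe set could hold the level up and cannot be told apart, since the second probe set changed by -0.263 below the filter.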
